A study of Mus musculus with 14 samples.

How the data were processed

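Polyadenylated RNA from mouse ventricles was sequenced as stranded paired-end libraries, in 14 libraries from 4 groups: Sham+GFP, TAC+GFP, Sham+JP2NT and TAC+JP2NT. Per the labels, the authors used FastQC 1.0.0, STAR 2.6.1a and Salmon with genome build mm10; the Salmon version, the annotation and the scaling software are not given in the sources used here. The deposited values are a signal derived from gene counts: the authors divided the counts by scale factors, separately within the 7 GFP libraries and the 7 JP2NT libraries. The values show this, since median-of-ratios factors are equal within each of these sets. The commonest low value of each library was taken as the value of 1 read, which gives about 8650189 to 14460609 reads per library. Divided by that value, 1.63% and 1.85% of the values above 0 in the GFP and JP2NT libraries lie within 0.001 of a whole number. Whole reads therefore cannot be recovered. The labels do not say whether each library comes from a separate mouse, so it is not known whether the samples are independent animals. The p-values treat them as independent.

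The table lists 24972 genes, 18188 of them above 0. Gene names had been turned into dates in 26 cases and 2 names occurred more than once. Genes with a value of at least 10 in at least 3 samples were tested, 13215 in all. Values were rescaled jointly over all samples by unweighted trimmed means of M-values (trimming 30% of ratios and 5% of mean levels), 1 was added, and log2 was taken. Differences were tested with limma-trend (limma 3.58.1 in R 4.3.3) with a mean per group and 1 spread for all groups, with 9 residual and 5.69 prior degrees of freedom. The median SD of log2 values within groups was 0.107 in Sham+GFP, 0.158 in TAC+GFP, 0.0836 in Sham+JP2NT and 0.176 in TAC+JP2NT. A spread shared by all groups is therefore too small for most genes in TAC hearts and too large in sham hearts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. All tests were two-sided. Group values are means of rescaled values with the SD. The p-values adjusted over genes come from limma, and those of gene lists from camera unless fry is named. Single values of Jph2 were compared with exact permutation tests; 3 against 2 samples cannot give a p under 0.1.

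The comparisons, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The plan named quasi-likelihood tests of a count model; because the deposited values are scaled and not whole, limma was used in their place. The plan also took the 14 libraries as separate samples. Sham+JP2NT replicates 1 and 2 were then found to differ by little more than counting noise, with a ratio of observed to counting variance of 1.22 over all genes with at least 50 reads and of 1.56 over abundant genes, where the other 17 pairs within groups had 1.72 to 7.34 and 7.23 to 136. They share no identical values. They were averaged and counted as 1 sample. This was found after results with 14 separate libraries had been seen, and the limit of 2 for the ratio over abundant genes was set after the ratios were seen. With 14 separate libraries 6462, 976, 0, 5374 and 125 genes were called in the 5 comparisons, in place of 6361, 807, 0, 4244 and 10. Replicates 1 and 2 of TAC+GFP and of TAC+JP2NT were the closest pairs of their groups but not within noise, and were averaged as an alternative only.

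The 5 comparisons were TAC against sham under each vector, JP2NT against GFP under each surgery, and the interaction of the factors. Genes called in TAC+GFP against Sham+GFP and, with the opposite sign, in TAC+JP2NT against TAC+GFP were counted. Since these comparisons share the TAC+GFP libraries, the count was set beside independent lists, simulated data without a vector effect, and the 6 assignments of the TAC+GFP libraries to the comparisons, 2 to each. The 40 gene lists comprised 22 of biological processes (hypertrophic stress, calcium handling and dyad, potassium and sodium channel, collagen and matrix, activated fibroblast, fatty acid oxidation, TCA cycle, oxidative phosphorylation, glycolysis, MEF2 factors and targets, interferon-stimulated, MHC class II, MHC class I and processing, cytokine and chemokine, cell cycle, unfolded protein response, oxidative stress response, autophagy and lysosome, angiogenesis, immediate early, circadian clock and mitochondrially encoded genes) and 18 of cell types found in or near the ventricle. Some genes are in several lists. Lists with at least 3 members tested, 38 in all, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and with fry beside it. A preset correlation of 0.01 calls more lists than an estimated one. Members were counted with adjustment over all genes and adjusted over the list alone.

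Named genes were Jph2, 6 genes fixed in advance (Nppa, Nppb, Myh7, Atp2a2, Col3a1 and Postn), up to 5 with the largest change in each direction among called, annotated genes with a mean of at least 1 on the log2 CPM scale in a group compared and no overlap between the groups, up to 4 called members of each list with the smallest p, the 10 steepest genes called in opposite directions, with the same limit on the mean in any of their groups, and the 5 genes with the smallest p where none was called. The limit on overlap between groups was not applied to genes named for the interaction. The genes of other tissues and of sampling conditions at the end of the other observations were chosen after their values were seen. Positions come from GENCODE M21 on mm10. Alternatives were other scalings, filters, pseudocounts, tools and spread models, a block by replicate number, fewer samples, and each library left out in turn. The tests recovered 75.8% of genes changed 2-fold and 49.3% of those changed 1.5-fold when checked on simulated data with the sample sizes of the TAC vector comparison, and 44.6% and 14.9% in the interaction. The simulated groups shared 1 spread per gene and the genes varied independently. Since the TAC groups varied more than the sham groups, recovery between TAC groups may be lower than this. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.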

Results

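RNA sequencing measured polyadenylated RNA in the ventricles of male C57BL/6N mice that had sham surgery or transverse aortic constriction (TAC), which narrows the aorta and loads the left ventricle with pressure. Surgery took place at 9 to 10 weeks of age. Echocardiography 2 weeks later selected 30 TAC mice with an ejection fraction between 40 and 60% and 10 sham mice with normal function. These mice then received an adeno-associated virus carrying either GFP, the control, or JP2NT, the N-terminal part of junctophilin-2, at 1e12 viral genomes in 100 ul by tail vein. Hearts were taken 8 weeks after surgery. Junctophilin-2 links the cell membrane to the sarcoplasmic reticulum of cardiomyocytes. The series asks whether JP2NT given after overload is established alters the failing heart.

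The 14 libraries comprised 3 Sham+GFP, 4 TAC+GFP, 3 Sham+JP2NT and 4 TAC+JP2NT libraries, with gene-assigned reads estimated from the value of a single read at 8650189 to 14460609 per library. Of 24972 genes listed, 13215 were abundant enough to test. Sham+JP2NT replicates 1 and 2 differed by little more than counting noise, with a variance ratio of 1.22 over all genes and 1.56 over abundant ones, where the other 17 pairs within groups had 1.72 to 7.34 and 7.23 to 136. They were counted as 1 sample, which leaves 13 samples and n = 2 in Sham+JP2NT. The first principal component held 50.6% of the variance and separated the surgeries. Sham libraries lay between -41.5 and -34.5 on it and TAC+GFP libraries between 35.2 and 45.9. TAC+JP2NT replicates 1 to 3 lay at 23.7, 23.4 and 27.5, and replicate 4 lay at -2.3, between the other TAC libraries and the shams. Transcripts of Myh6, the adult cardiac myosin heavy chain, made up 3.93 to 4.37% of the total in sham libraries, 1.32 to 1.86% in TAC+GFP libraries and 1.76 to 3.07% in TAC+JP2NT libraries, highest in replicate 4.

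**Figure D1:**
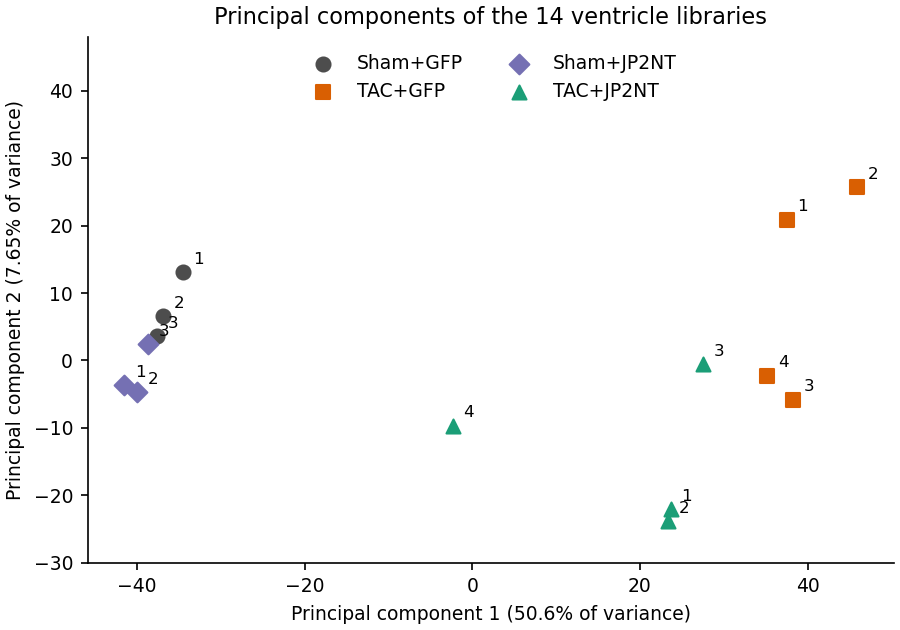
Principal components 1 and 2 of log2 values in the 14 libraries, in units of the component scores; each point is a library, numbered by replicate. TAC+JP2NT replicate 4 sits at -2.3 on the first component, between the shams and the other TAC libraries.

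Jph2, which encodes junctophilin-2 (chromosome 2 from 163336242 to 163397993, minus strand, mm10), was not higher in the hearts that received JP2NT. Its normalised value was 7893 ± 254 (SD, n = 3) in Sham+GFP, 6154 ± 342 (n = 4) in TAC+GFP, 7042 ± 203 (n = 2) in Sham+JP2NT and 6345 ± 318 (n = 4) in TAC+JP2NT. Under GFP, TAC lowered it by -0.36 on the log2 scale (adjusted p = 0.000319; two-sided exact permutation p = 0.0286, the smallest possible). Between vectors the log2 difference was 0.04 in TAC hearts (95% interval -0.08 to 0.17; exact permutation p = 0.429) and -0.16 in sham hearts (95% interval -0.33 to -0.0036; exact permutation p = 0.1, the smallest possible). The sources used here do not say whether reads of the JP2NT insert were counted as Jph2.

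**Figure D2:**
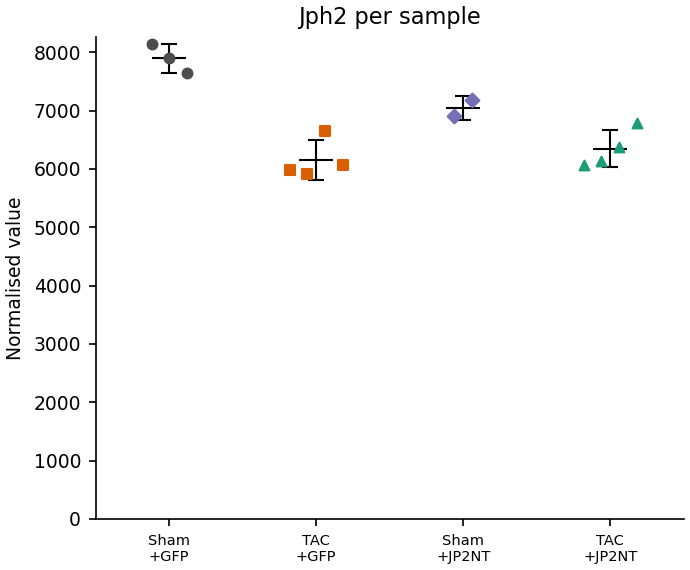
Normalised value of Jph2 in each of the 13 samples by group; points are samples, horizontal bars the mean and error bars the SD. The TAC+JP2NT mean of 6345 lies within the spread of TAC+GFP.

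The first comparison asks how 8 weeks of pressure overload changed the ventricle under the control virus. The fetal and stress program of cardiomyocytes rose steeply in TAC+GFP. Myh7, the fetal myosin heavy chain, went from 2250 ± 315 (n = 3) to 84140 ± 17400 (n = 4), a 36.9-fold rise, while Myh6 fell 2.8-fold. The natriuretic peptide genes Nppa and Nppb rose 14.6-fold and 9.45-fold. Ctgf, a matricellular growth factor, rose 13.5-fold and Ankrd1, a sarcomeric stress protein, 5.54-fold. Of 13215 genes tested, 3118 rose and 3243 fell (limma, adjusted p under 0.05), and 823 rose and 391 fell at least 2-fold. Leaving out single libraries gave 5201 to 6676 genes.

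Of the 16 hypertrophic stress genes, 15 rose, and 15 adjusted over the list alone (median log2 fold change 2.36; camera adjusted p = 2.84e-11, and adjusted p = 0.41 with an estimated correlation). Potassium and sodium channel genes moved the other way: 15 of 18 fell and 2 rose, the same numbers adjusted over the list alone (median -0.69; adjusted p = 0.000164, and adjusted p = 0.41 with an estimated correlation). Scn4b, a sodium channel beta subunit, fell from 1092 ± 1.25 to 222.6 ± 40.7, Kcnj2, an inward rectifier, fell 2.6-fold, and Kcnip2, an auxiliary subunit of Kv4 channels, fell 1.92-fold. Among calcium handling and dyad genes, 4 rose and 7 fell of 18 (5 and 7 adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.611; its median of 0.09 and mean of -0.06 differ in sign). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell from 243400 ± 5250 to 114200 ± 16200, and Hrc and Pln fell 2.56-fold and 1.49-fold. Cacna2d1, an auxiliary calcium channel subunit, rose 1.57-fold. Of the 18 MEF2 factors and described MEF2 target genes, 7 rose and 5 fell, alone in the list as over all genes, with Xirp2 up 5.01-fold and Slc2a4 down 1.98-fold (adjusted p = 0.979 for the list, whose median of 0.06 is positive and whose test points down).

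Of 33 collagen and matrix genes 29 rose and 1 fell (29 and 1 adjusted over the list alone; median 1.01; adjusted p = 1.16e-10, and adjusted p = 0.49 with an estimated correlation). Ltbp2, a latent TGF-beta binding protein, rose 20.1-fold, Thbs4 13-fold, Mfap4 7.86-fold and Col3a1 2.01-fold. Of 19 activated fibroblast genes 16 rose and 2 fell (16 and 2 adjusted over the list alone; median 1.95; adjusted p = 2.02e-07, and adjusted p = 0.41 with an estimated correlation). Periostin, encoded by Postn, went from 500.3 ± 31.9 to 5126 ± 1690, and the matrix genes Comp and Cilp rose 11.9-fold and 7.57-fold, whereas Acta2 fell 2.04-fold. Of 12 fibroblast markers, Mfap4 and other matrix genes among them, 8 rose and 1 fell, likewise adjusted over the list alone. Their median was 0.41 (camera adjusted p = 0.0131, and adjusted p = 0.49 with an estimated correlation). Whether it differed from that of the activated fibroblast genes was not tested. Cell cycle genes rose as well, 20 up and 1 down of 25 with the same numbers adjusted over the list alone (median 1.33; adjusted p = 3.05e-05, and adjusted p = 0.49 with an estimated correlation), from low levels: Mki67 went from 39.46 ± 3.99 to 199.6 ± 96.4. Relative to the Sham+GFP mean, the mean over the cell cycle genes was 2.13 in TAC+GFP replicate 4 and 1 to 1.1 in the other TAC+GFP libraries, and without replicate 4 the median was 1.09. Of 17 immediate early genes 10 rose, and 10 adjusted over the list alone (adjusted p = 0.00286, and adjusted p = 0.546 with an estimated correlation), among them Atf3 at 5.87-fold. The rise was absent as a list mean in TAC+GFP replicate 3: relative to the Sham+GFP mean, its mean over these genes was -0.04 on the log2 scale, within the -0.09 to 0.11 of the Sham+GFP libraries, against 0.896 to 1.43 in the other TAC+GFP libraries.

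Of 26 fatty acid oxidation genes 21 fell and none rose (22 and 0 adjusted over the list alone; median -0.71; adjusted p = 2.27e-10, and adjusted p = 0.456 with an estimated correlation), with Cpt2, the inner-membrane carnitine palmitoyltransferase, down 2.2-fold and Acsl1 down 2.13-fold. Of 20 TCA cycle genes 17 fell, and 17 adjusted over the list alone (median -0.44; adjusted p = 1.52e-07, and adjusted p = 0.49 with an estimated correlation), with citrate synthase, encoded by Cs, down 1.72-fold. Of 32 oxidative phosphorylation genes 21 fell (22 adjusted over the list alone; median -0.34; adjusted p = 1.11e-05, and adjusted p = 0.49 with an estimated correlation), among them Uqcrc1 of complex III at 1.61-fold. Glycolysis genes split, with 3 up and 9 down of 19, alone in the list as over all genes (median -0.15; adjusted p = 0.027, adjusted p = 0.49 with an estimated correlation, and, without TAC+GFP replicate 3, median -0.12 and adjusted p = 0.0553), and the glucose transporter gene Slc2a4 was among those that fell. Cardiomyocyte markers fell in 6 of 14 genes and rose in 1, with the same numbers adjusted over the list alone (median -0.20; adjusted p = 0.027, and adjusted p = 0.49 with an estimated correlation). Of 9 pericyte markers 7 fell, and 7 adjusted over the list alone (median -0.47; adjusted p = 0.00057, and adjusted p = 0.456 with an estimated correlation), among them Abcc9, 2-fold, and Notch3, 1.96-fold.

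Steep single increases outside these lists were found in Nmrk2, a nicotinamide riboside kinase, at 41.3-fold, and in the chemokine receptor gene Cxcr6, which went from a value of 1.99 ± 1.69 to 100.1 ± 19.7. Sprr1a, a small proline-rich protein, went from 0.342 ± 0.592 to 309.8 ± 165. Steep decreases were found in the Nogo receptor gene Rtn4r, 13-fold, and in the chemokine gene Ccl11 and in Shisa6, which fell to values of 1.92 ± 0.159 and 1.66 ± 0.429. Zbed6, which lies inside another gene, and Zfp781, which has close paralogs, also ranked there, and reads of their neighbours and copies cannot be told from their own in the table.

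The second comparison asks what JP2NT altered in overloaded hearts. Several stress and matrix genes, Nppa, Nppb, Myh7 and Postn among them, were lower in TAC+JP2NT than in TAC+GFP and higher than in Sham+JP2NT. Nppa stood at 29030 ± 10400 against 81150 ± 29000 in TAC+GFP (n = 4 each; log2 fold change -1.46, adjusted p = 0.00874), Nppb was 1.95-fold lower and Myh7 1.65-fold lower. Between vectors in sham hearts Nppb was 1.66-fold lower with JP2NT, while Nppa and Myh7 were 1.47-fold and 1.27-fold higher. None of these passed the test (limma adjusted p = 0.999 each). In TAC hearts Ctgf was 2.77-fold lower and Postn 2.13-fold lower. Lgals3, which encodes galectin-3, a lectin of macrophages and fibrosis, stood at 127.2 ± 24.9 against 387.8 ± 98.4 (log2 fold change -1.59, adjusted p = 0.000359). Scn4b, in contrast, was 2.46-fold higher, at 543.2 ± 40.5 against 222.6 ± 40.7 (adjusted p = 4.7e-05). Atp2a2 was 1.28-fold higher, which did not pass the test (adjusted p = 0.0802).

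In all, 366 genes were higher and 441 lower in TAC+JP2NT than in TAC+GFP, 31 and 59 of them at least 2-fold. The deposited values had been scaled separately for the libraries of each vector, which is confounded with this comparison, and were rescaled jointly here; taken as deposited they gave 226 higher and 1191 lower genes. The count of 807 fell to 264 without TAC+GFP replicate 2 and to 380 without TAC+GFP replicate 1. It fell to 446 without TAC+JP2NT replicate 2 and to 482 without TAC+JP2NT replicate 1. The TAC groups varied more than the sham groups, so 1 spread for all groups favours calls in this comparison. With the spread estimated per group 419 genes were called, and with only the compared groups in the model 196. When the closest TAC libraries, replicates 1 and 2 of each vector, were averaged, 157 were called.

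**Figure D3:**
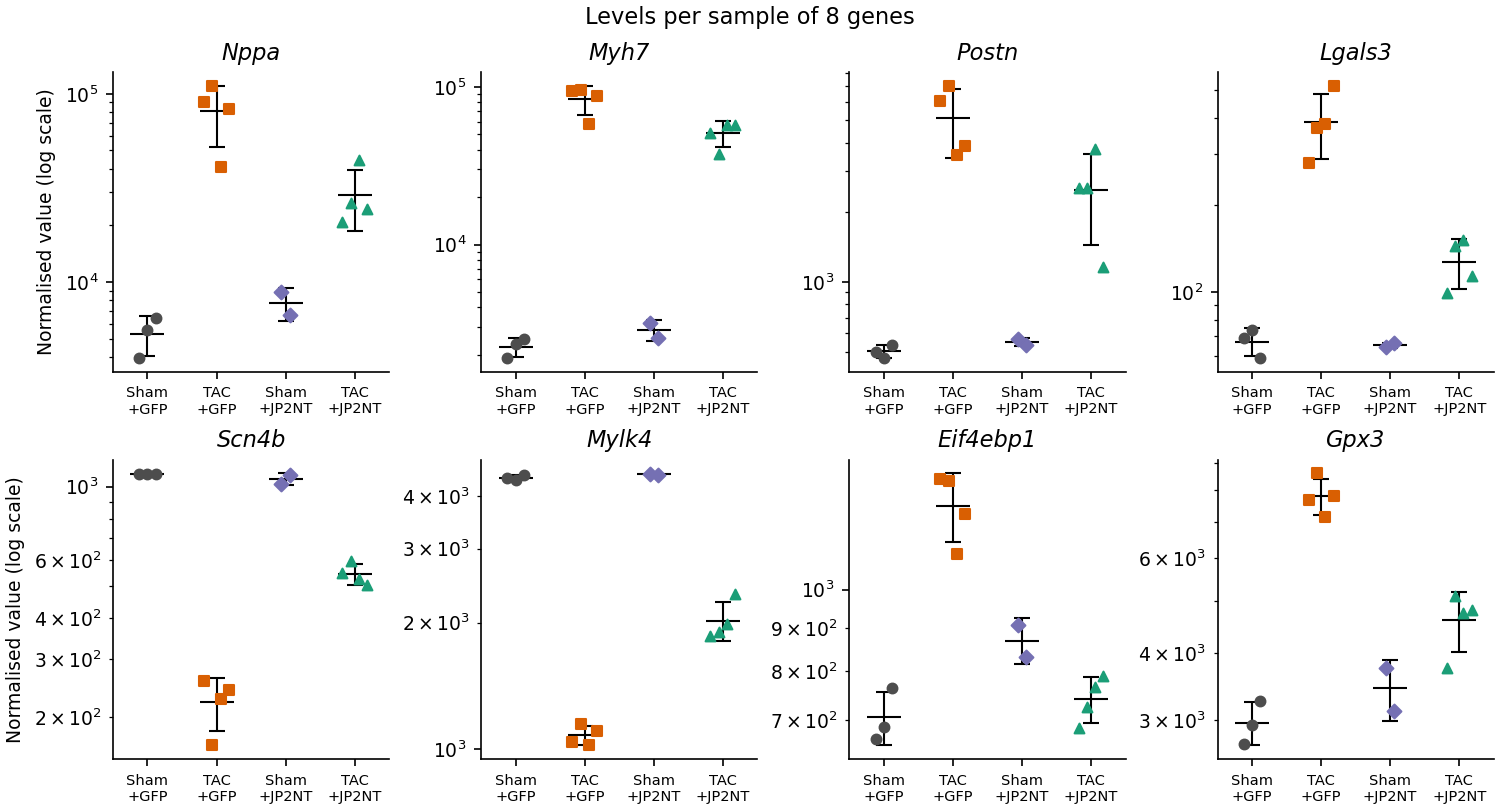
Normalised values, on log axes, of 8 genes in the 13 samples by group; points are samples, horizontal bars the mean and error bars the SD. In TAC+JP2NT, Nppa, Myh7, Postn, Lgals3, Eif4ebp1 and Gpx3 lie below TAC+GFP and Scn4b and Mylk4 above it.

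Collagen and matrix genes fell in 13 of 33 cases and rose in none (18 and 1 adjusted over the list alone; median -0.53; adjusted p = 1.99e-09, and adjusted p = 0.717 with an estimated correlation). The libraries of the groups overlapped: relative to the Sham+GFP mean, the list mean was 1.26 on the log2 scale in TAC+JP2NT replicate 3, above TAC+GFP replicates 3 and 4 at 1.23 and 1.07, and 0.33 in TAC+JP2NT replicate 4, below 0.80 and 0.83 in replicates 1 and 2. Without TAC+JP2NT replicate 4 the median was -0.37, and without replicate 3 -0.69. Lox, which cross-links collagen, was 3.99-fold lower, the metalloprotease inhibitor gene Timp1 3.31-fold lower and Eln, elastin, 2.3-fold lower. Of 19 activated fibroblast genes 8 were lower and 1 higher (11 and 1 adjusted over the list alone; median -0.66; adjusted p = 1.22e-06, and adjusted p = 0.333 with an estimated correlation). Comp was 3.02-fold lower and the collagen receptor gene Ddr2 1.32-fold higher. Of 16 hypertrophic stress genes 5 were lower and none higher (10 and 0 adjusted over the list alone; median -0.61; adjusted p = 9.26e-08, and adjusted p = 0.333 with an estimated correlation). These libraries overlapped as well, with list means of 2.17 in TAC+JP2NT replicate 3 and 1.96 in TAC+GFP replicate 3, and TAC+JP2NT replicate 4 was lowest at 1.39. For activated fibroblast genes TAC+JP2NT replicate 4 lay at 0.69, and the other libraries of the group at 1.34 to 1.52, below the 1.76 to 2.18 of TAC+GFP. The list of fibroblast markers was not called (camera adjusted p = 0.957), with 1 of 12 lower (3 adjusted over the list alone). Its median of 0.08 and mean of -0.08 differ in sign.

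Autophagy and lysosome genes were lower in TAC+JP2NT and formed the list whose call also held with an estimated correlation. Of 17 genes 5 were lower and none higher (9 and 0 adjusted over the list alone; median -0.23; adjusted p = 6.31e-07, and adjusted p = 0.0141 with an estimated correlation). They included Ctsl, Ctsk and Ctsd, lysosomal cathepsins, at 1.29-fold, 1.7-fold and 1.25-fold, and Bnip3, a mitophagy receptor, at 1.66-fold. Glycolysis genes were lower in 8 of 19 cases and higher in 1 (12 and 5 adjusted over the list alone; median -0.22; adjusted p = 0.00138, and adjusted p = 0.434 with an estimated correlation), with the glucose transporter gene Slc2a1 1.89-fold lower and Eno1 1.37-fold lower. Of 17 immediate early genes 1 was lower, Ier3 at 1.76-fold, and 1 adjusted over the list alone (median -0.46; adjusted p = 0.00109, and adjusted p = 0.827 with an estimated correlation). The list mean was -0.36 in TAC+JP2NT replicate 3 and 0.60 to 0.83 in the rest of the group. The median was -0.24 without that library, where the list was not called (adjusted p = 0.0963), and -0.70 without TAC+GFP replicate 3.

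Of 18 potassium and sodium channel genes 3 were higher and none lower (6 and 0 adjusted over the list alone; median 0.22; adjusted p = 0.00109, and adjusted p = 0.333 with an estimated correlation), namely Scn4b, Kcnd2 at 1.69-fold and Hcn2 at 1.36-fold. Of 9 pericyte markers 3 were higher, Abcc9, Notch3 and Vtn, and none lower (7 and 0 adjusted over the list alone). Their median was 0.28 (camera adjusted p = 1.09e-05, and adjusted p = 0.333 with an estimated correlation). The RNA came from ventricles, so the values do not tell in which cells these genes differed. Among endothelial markers Egfl7 was 1.35-fold lower, and that list was not called here but was in 4 of 19 alternative settings. Lgals3 was the single member called of 20 macrophage markers. The macrophage list was not called here, and was called in 0 of 19 alternative settings (camera adjusted p = 0.0701 to 0.736). Among calcium handling genes Hrc and Pln were 1.37-fold and 1.24-fold higher and Cav3 1.24-fold lower (4 up and 2 down adjusted over the list alone; adjusted p = 0.572 for the list). Fatty acid oxidation genes were higher as a list (median 0.12; adjusted p = 0.0207, and adjusted p = 0.827 with an estimated correlation), with Cpt2, 1.28-fold, the single member called, alone in the list as over all genes. That list call was lost without TAC+JP2NT replicate 4 (median 0.06; adjusted p = 0.498), TAC+GFP replicate 3 (median 0.09; adjusted p = 0.209) or TAC+GFP replicate 4 (median 0.10; adjusted p = 0.0588), and the list means of the libraries overlapped, at -0.78 to -0.44 in TAC+JP2NT and -0.91 to -0.60 in TAC+GFP. None of the 20 TCA cycle and none of the 32 oxidative phosphorylation genes was called by limma or adjusted over the list alone (adjusted p = 0.369 and 0.81 for the lists; the median of 0.0038 and mean of -0.006 of the latter differ in sign). Of 18 MEF2-related genes 2 were higher and 3 lower (3 and 5 adjusted over the list alone; adjusted p = 0.732 for the list, whose median of 0.03 and mean of -0.09 differ in sign), the latter being Des, Smpx and Xirp1.

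Among genes with a mean of at least 1 on the log2 CPM scale in either group, and no overlap of samples between the groups, the largest decreases were in the protease inhibitor genes Serpina3i, 6.42-fold, and Serpina3n, 5.2-fold, Tmem252, 5.71-fold, Cthrc1, a fibroblast activation gene, 5.18-fold, and Lcn2, lipocalin-2, 4.68-fold. The largest increases among them were in Rtn4r, 3.45-fold, the water channel gene Aqp4, 3.23-fold, the hedgehog effector Gli1, 2.62-fold, Ky, 2.61-fold, and Snai3, 2.47-fold. Serpina3i and Serpina3n belong to a cluster of near-identical genes that can share reads.

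Most of the genes that differed between vectors in TAC hearts ran against the overload response. Of the 807, 352 had risen with TAC under GFP and were lower with JP2NT, 297 had fallen and were higher, and 12 had changed in the same direction. The 649 genes with opposite signs became 227 without TAC+GFP replicate 2, 336 without TAC+GFP replicate 1, 392 without TAC+JP2NT replicate 2, 420 without TAC+JP2NT replicate 1 and 145 with the closest TAC libraries averaged. They numbered 524 without TAC+JP2NT replicate 4 and 376 with the spread estimated per group. Besides Serpina3i, Serpina3n, Ccl11, Tmem252, Cthrc1 and Lcn2, the steepest of these were Sprr1a, which stood at 48.11 ± 36.9 in TAC+JP2NT against 309.8 ± 165, Nmrk2, 5.03-fold lower, Star, 4.64-fold lower, and Adgra1, 4.29-fold lower. By list they comprised 13 of 33 collagen and matrix genes, 9 of 19 activated fibroblast genes, 5 of 16 hypertrophic stress genes and 3 of 9 pericyte markers, and 0 of the oxidative phosphorylation, TCA cycle and cell cycle genes. Independent lists of these sizes would share 104 and 90 genes in the 2 directions. The comparisons share the TAC+GFP libraries with opposite sign, which alone gives a covariance of the log2 fold changes of -0.02 in simulations, against -0.14 observed, a difference of -0.12. The simulated genes varied independently, with 1 spread per gene for all groups, which is too small for most genes in TAC hearts. The simulations therefore do not show what covariance arises when genes vary together between hearts. Split so that they shared no library, the 6 assignments gave 82 to 597 such genes, with covariances of -0.13 to -0.11.

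The third comparison was the overload response under JP2NT, in which the hypertrophic stress, matrix and activated fibroblast lists were again called. Myh7 rose from 2864 ± 434 (n = 2) to 50880 ± 9470 (n = 4), and Nppb, Nppa and Postn rose 8.03-fold, 3.62-fold and 4.18-fold. Atp2a2 fell from 251400 ± 6740 to 145700 ± 16600. Col3a1 had a log2 fold change of 0.63 that did not pass the test (adjusted p = 0.0583). Sprr1a, listed at 0 in both Sham+JP2NT samples, reached 48.11 ± 36.9. The acyl-CoA thioesterase gene Acot1 fell from 314.2 ± 5.06 to 40.25 ± 22.6. Uckl1os, an antisense transcript, for which the sources used here do not say whether reads were assigned by strand, fell 6.46-fold.

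Of 13215 genes 2101 rose and 2143 fell, 438 and 188 of them at least 2-fold. With Sham+JP2NT replicate 3 left out, so that the lone remaining sham sample was assumed to vary like the other groups, the count of 4244 fell to 1882, and without the averaged pair to 1964. Hypertrophic stress genes rose in 15 of 16 cases (16 adjusted over the list alone; adjusted p = 2.99e-13, and adjusted p = 0.364 with an estimated correlation), collagen and matrix genes in 17 of 33 (28 adjusted over the list alone; adjusted p = 5e-10, and adjusted p = 0.535 with an estimated correlation) and activated fibroblast genes in 12 of 19, with Acta2 falling (13 and 1 adjusted over the list alone; adjusted p = 2.96e-06, and adjusted p = 0.364 with an estimated correlation). Fatty acid oxidation genes fell in 22 of 26 cases (22 adjusted over the list alone; adjusted p = 3.92e-12, and adjusted p = 0.364 with an estimated correlation) and glycolysis genes in 12 of 19, with 2 rising (15 and 2 adjusted over the list alone; adjusted p = 9.93e-06, and adjusted p = 0.364 with an estimated correlation).

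Set beside each other, the responses under the 2 vectors shared 1743 genes that rose and 1777 that fell, where independent lists would share 496 and 526, and 3 genes changed in opposite directions; the comparisons share no library. Over all called genes the relative size of the responses depended on the selection. Of the 6361 genes called under GFP 79.1% responded less under JP2NT, with a median ratio of 0.715 of JP2NT to GFP, whereas of the 4244 called under JP2NT 53.1% did, with a median ratio of 1.04 of GFP to JP2NT. Without TAC+JP2NT replicate 4 these were 71.2% and 0.784, and 44.2% and 0.936. Median list responses were smaller under JP2NT for activated fibroblast genes, 1.24 against 1.95, for hypertrophic stress genes, 1.92 against 2.36, and for collagen and matrix genes, 0.68 against 1.01. Tested as interactions, these differences were called (adjusted p = 0.000295, 0.00603 and 0.000295), but not with an estimated correlation (0.55, 0.828 and 0.828). Without TAC+JP2NT replicate 4 the median interactions went from -0.56, -0.26 and -0.38 to -0.26, -0.15 and -0.22, and the last 2 lists were not called (adjusted p = 0.0985 and 0.106). They lay close together for fatty acid oxidation genes, -0.66 against -0.71, and TCA cycle genes, -0.41 against -0.44.

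**Figure D4:**
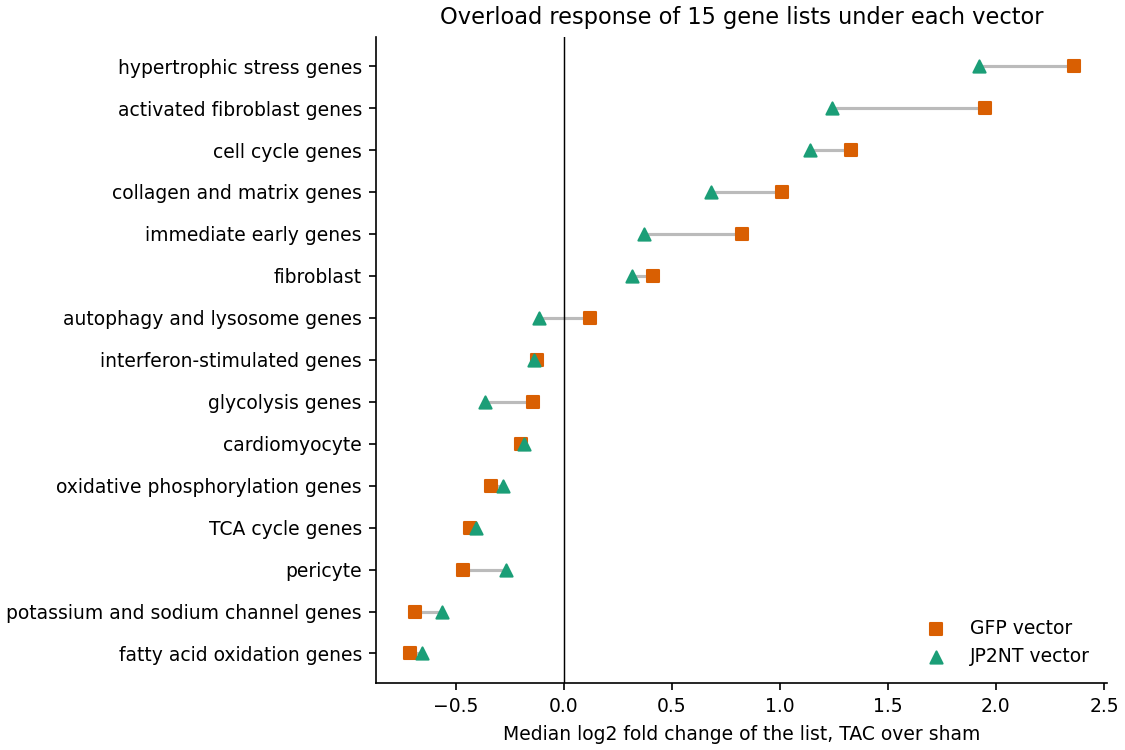
Median log2 fold change of TAC over sham for 15 gene lists fixed beforehand; squares are the GFP vector, triangles the JP2NT vector, and a grey line joins them. The activated fibroblast list moves from 1.95 to 1.24 and the fatty acid oxidation list from -0.71 to -0.66.

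The interaction tests whether the overload response itself differed between vectors, and 10 genes passed it. All 10 had changed with TAC under GFP, and each interaction had the sign opposite to that change, which it contains with opposite sign; such a direction is therefore favoured by the shared libraries and was not tested by itself. Under JP2NT 6 of them changed in the same direction as under GFP, by less. Retreg1, which rose under GFP, fell under JP2NT (log2 fold changes 0.48 and -0.42), and Cpox, Eif4ebp1 and Hist1h1c did not pass the test there (adjusted p = 0.336, 0.077 and 0.0696). Scn4b (chromosome 9 from 45138395 to 45154152) had fallen to 222.6 ± 40.7 with GFP and fell to 543.2 ± 40.5 with JP2NT, an interaction of 1.35 (adjusted p = 0.00959). Mylk4, a myosin light chain kinase of the heart (chromosome 13 from 32700834 to 32783954), fell from 4427 ± 61.6 to 1078 ± 58.4 under GFP and from 4506 ± 32.9 to 2021 ± 216 under JP2NT (interaction 0.88, adjusted p = 0.00959). Eif4ebp1, which encodes the translation repressor 4E-BP1 (chromosome 8 from 27260329 to 27276674), went from 705.7 ± 51.6 to 1256 ± 117 under GFP and stood at 870.4 ± 54.2 and 742.2 ± 46.2 under JP2NT (interaction -1.06, adjusted p = 0.00745). Efhd2, a calcium-binding protein of the actin cytoskeleton, had an interaction of -1.25, the plasma glutathione peroxidase gene Gpx3 of -0.98, the ER-phagy receptor gene Retreg1 of -0.90 and the linker histone gene Hist1h1c of -0.85. Rtn4r, the sulfotransferase gene Gal3st3 and the haem synthesis gene Cpox had interactions of 2.598, 1.27 and 0.70. Nppa and Myh7 had interactions of -2.02 and -1.07, which did not pass the test (adjusted p = 0.107 and 0.155). Nor did Nppb, Col3a1, Postn and Atp2a2, at -0.24, -0.38, -1.23 and 0.31 (limma adjusted p = 0.791, 0.712, 0.323 and 0.565).

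Of the gene lists, autophagy and lysosome genes differed between vectors in their overload response, with a median interaction of -0.26 (adjusted p = 4.6e-06, and adjusted p = 0.0175 with an estimated correlation), though none of the 17 was called by limma over all genes and 3 were lower adjusted over the list alone. The interaction count rested on few samples. It was 0 without Sham+GFP replicate 2, 0 without Sham+JP2NT replicate 3, 4 without Sham+GFP replicate 1, TAC+GFP replicate 2 or TAC+JP2NT replicate 2, 5 without Sham+GFP replicate 3 and 6 without TAC+GFP replicate 1, against 19, 57 and 49 without TAC+GFP replicate 4, TAC+GFP replicate 3 and TAC+JP2NT replicate 3, and 125 with all 14 libraries separate.

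The last comparison asks what JP2NT changed in hearts without overload. Limma called 0 genes between Sham+JP2NT (n = 2) and Sham+GFP (n = 3), with 551 at an unadjusted p under 0.05, where chance gives 661, and 0 by limma-voom. The sham groups varied less than the TAC groups, so 1 spread for all groups makes calls less likely here. With the spread estimated per group 0 genes were called as well. Nppb stood at 2047 ± 709 with JP2NT and 3321 ± 576 with GFP, Nppa at 7761 ± 1510 and 5318 ± 1260, and Myh7 at 2864 ± 434 and 2250 ± 315 (adjusted p = 0.999 each). The genes with the smallest p did not pass either: Rab30, Alpl, Hacd1, Mapk4 and Tnfrsf12a had log2 fold changes of -0.82, -0.39, -0.37, -0.54 and -0.63 (adjusted p = 0.999 each). In simulated data with these sample sizes and 1 spread for all groups, the test recovered 66.7% of genes changed 2-fold and 0% of those changed 1.25-fold. As lists, interferon-stimulated genes (median 0.23; adjusted p = 0.000208, and adjusted p = 0.737 with an estimated correlation) and MHC class II genes (median 0.54; adjusted p = 0.000213, and adjusted p = 0.737 with an estimated correlation) were higher with JP2NT, and unfolded protein response genes were lower (median -0.14; adjusted p = 0.00142, and adjusted p = 0.521 with an estimated correlation), with no member called, adjusted over the list alone included. Without the averaged pair these list calls were lost (medians 0.12, 0.34 and -0.07; adjusted p = 0.191, 0.104 and 0.123 in that order). Fry called none of the 38 lists tested.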

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

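The tests of explanations in this part were chosen after the results were seen; the interaction tests were planned.

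TAC+JP2NT replicate 4 stood apart from its group, at -2.3 on the first principal component where the other libraries of the group lay at 23.4 to 27.5. A sham library with the wrong label is argued against: of 823 genes at least 2-fold up in TAC+GFP, 76.9% exceeded the highest sham sample in this library, against 11.3 to 28.9% in the sham samples and 87.1 to 91.5% in the other TAC+JP2NT libraries. TAC RNA mixed with sham RNA cannot be told apart from a milder response: the share of the group's response, over 116 abundant genes, had a 90th to 10th percentile ratio of 4.06, and the other 3 libraries had 1.64, 1.75 and 4.23. Its median share was 0.578, while its share for Myh7 was 1.19. A smaller response of this heart stays open as well, since no measure of the load per animal was analysed here. Without this library 727 genes were called between vectors in TAC hearts, against 807 with it, and 563 were called both ways. Genes with opposite signs fell from 649 to 524.

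Genes called between vectors in TAC hearts mostly ran against the overload response, 649 of 807. The TAC+GFP libraries shared by these comparisons are argued against as the whole cause, since the covariance of the log2 fold changes stayed at -0.11 or below in the 6 splits that share none. The authors' separate scale factors for the libraries of each vector are argued against as the whole cause. Such factors move all genes of a library one way. With values as deposited, which were not rescaled jointly, the median of all genes was -0.08 between vectors in TAC hearts, and 186 genes with opposite signs were higher with JP2NT, against that shift, beside 774 that were lower. Milder pressure overload in the TAC+JP2NT animals cannot be told apart from an effect of the vector on the response, since the labels give a single range of ejection fraction for the TAC mice. It predicts few genes that change in the same direction in both comparisons. There were 12, a number that the shared libraries hold down, and 0, 1, 5, 1, 1 and 70 in the splits that share none, the 70 being out of 1147 genes. An effect of JP2NT on the overloaded heart may account for the pattern and stays a hypothesis.

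Jph2 was not higher with the JP2NT vector. Abundant reads of the insert counted as Jph2 are argued against, since the upper 95% bound of the log2 difference in TAC hearts was 0.17, below the 0.585 of a 1.5-fold rise. Reads of the insert that were not counted as Jph2, or were too few, cannot be told apart from the absence of the insert's RNA: the log2 difference was 0.0444 and the table does not separate the insert from the endogenous gene. No biological explanation was tested.

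For the counts of called genes, the real grouping gave a share of 1 in 35 splits, the smallest that 35 splits can give. This lies under 0.05 and argues against chance, without excluding it, only if the libraries are independent. With the closest TAC libraries averaged 157 genes were called between vectors in TAC hearts. Of 35 splits of the Sham+GFP and TAC+GFP libraries, 1, the real one, gave as many genes, 6361 against at most 3147 in the others. Of 35 splits of the TAC libraries 1, the real one, gave as many genes between vectors, 807 against at most 185. As many genes with opposite signs, 649, were likewise found in 1, the real one, against at most 152 in the others, but these genes are among those called between vectors and no other split could reach that number. The splits therefore do not tell whether the direction is particular to the real grouping. Genes with opposite signs made up 80.4% of those called in the real split and, in the other splits with most genes, 82.2% of 185, 26.3% of 19 and 50% of 14.

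The overload response differed between vectors, by the test of the interaction, in 10 genes: Cpox (0.70), Efhd2 (-1.25), Eif4ebp1 (-1.06), Gal3st3 (1.27), Gpx3 (-0.98), Hist1h1c (-0.85), Mylk4 (0.88), Retreg1 (-0.90), Rtn4r (2.598) and Scn4b (1.35), on the log2 scale. It also differed in 6 gene lists, of which autophagy and lysosome genes (adjusted p = 4.6e-06, and adjusted p = 0.0175 with an estimated correlation) kept the call with an estimated correlation. The others lost it: hypertrophic stress genes (0.00603, and adjusted p = 0.828 with an estimated correlation), collagen and matrix genes (0.000295, and adjusted p = 0.828 with an estimated correlation), activated fibroblast genes (0.000295, and adjusted p = 0.55 with an estimated correlation), unfolded protein response genes (0.0129, and adjusted p = 0.55 with an estimated correlation) and pericyte markers (0.00148, and adjusted p = 0.55 with an estimated correlation). Members adjusted over the list alone numbered 4, 4, 5, 2 and 1. Without TAC+JP2NT replicate 4 the first 2 of these lists were not called (medians -0.15 and -0.22, from -0.26 and -0.38; adjusted p = 0.0985 and 0.106), and without the averaged Sham+JP2NT pair unfolded protein response genes were not (median 0.16, from 0.14; adjusted p = 0.106).

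Single samples lay far from the rest of their group of 4 in 18 of 222 groups tested, the component included, where chance gives 11.1, or about 1 in 20. In TAC+JP2NT replicate 3 these were the values of Csf1 (963.9), Ctsd (22210), Eln (1017), Serpina3i (12.6), Ier3 (292.9) and Notch3 (587.2), the last 2 lowest and the others highest. In TAC+GFP replicate 3 they were Ccl8 (139.4, highest), Acot1 (15.3) and Snai3 (9.33, both lowest). The others were highest in their group: Acot1 in TAC+JP2NT replicate 4 (74.1), Egfl7 in TAC+JP2NT replicate 1 (956.2), Timd4 in TAC+JP2NT replicate 2 (22.9), Kdr (2271) and Slc2a4 (4077) in TAC+GFP replicate 1, Rab30 in TAC+GFP replicate 2 (100.8), and Psmb10 (878.2) and Timd4 (18.3) in TAC+GFP replicate 4.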

How the results depend on the processing

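The 14 separate libraries were the planned samples, and became an alternative when the pair was averaged. The settings with closest TAC libraries averaged, the averaged pair left out, a spread per group, values as deposited, other pseudocounts and the first residual component were chosen after seeing the data; the others were planned. DESeq2 and sva were not run. No called result reversed, and where no cause is given the cause was not tested. Of 53 list calls, 2 were kept with an estimated correlation and 33 by fry; the autophagy list was called in all 19 settings tried in the TAC vector comparison (adjusted p = 1.5e-07 to 2.94e-06) and the interaction (3.26e-07 to 4.66e-05). The log2 difference of Jph2 between vectors in TAC hearts was 0.01 to 0.08 with single libraries left out and -0.04, of the other sign, with values as deposited; it was not called.

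A log2 fold change of at least 1 as well, which is stricter, left 1214 genes in TAC+GFP against Sham+GFP, 90 between vectors in TAC hearts, 626 in TAC+JP2NT against Sham+JP2NT, 5 in the interaction and 75 with opposite signs. An adjusted p under 0.1, which is looser, gave 1583 between vectors in TAC hearts, 35 in the interaction and 1241 opposite. With the closest TAC libraries averaged as well, which leaves fewer samples, the counts were 157, 4 and 145 in that order, and with the spread estimated per group 419, 81 and 376. The first residual component as covariate gave 1280, 39 and 1018. Only the groups compared gave 196 between vectors in TAC hearts and 1 in sham hearts (Rnaset2a); values as deposited gave 1417 in TAC hearts. Without the averaged Sham+JP2NT pair there were 2 genes between vectors in sham hearts (Btg3 and Tnfsf13), 1964 in TAC+JP2NT against Sham+JP2NT and 0 in the interaction (limma). The interaction had 6 genes with no low-value filter, 125 with all 14 libraries separate and 87 with a replicate block on these. Deviations from the group mean had a median correlation of 0.009 between libraries with the same replicate number and -0.011 between others. These values give no sign of pairing by number, but do not exclude a shared order of handling. Splits of the TAC+GFP libraries between the comparisons, with replicates 1 and 2, 1 and 3, 1 and 4, 2 and 3, or 2 and 4 set against sham, gave 106, 166, 388, 82 and 122 opposite genes.

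With single libraries left out, TAC+GFP against Sham+GFP had 5201 to 6676 genes. The TAC vector comparison had 264 (without TAC+GFP replicate 2) to 1069, and opposite genes 227 (without the same library) to 866; without TAC+GFP replicate 1 they were 380 and 336, without TAC+JP2NT replicate 2 446 and 392, and without TAC+JP2NT replicate 1 482 and 420. The sham vector comparison had 0 to 1, the 1 being Gm3055 without Sham+GFP replicate 3. TAC+JP2NT against Sham+JP2NT had 1882 (without Sham+JP2NT replicate 3, the lone sample being assumed to vary like the other groups) to 5016. The interaction had 0 (without Sham+GFP replicate 2 or Sham+JP2NT replicate 3) to 57 (without TAC+GFP replicate 3), with 4 without Sham+GFP replicate 1, TAC+GFP replicate 2 or TAC+JP2NT replicate 2, 5 without Sham+GFP replicate 3, 6 without TAC+GFP replicate 1, 19 without TAC+GFP replicate 4 and 49 without TAC+JP2NT replicate 3. Eif4ebp1, Mylk4 and Scn4b were called in all settings with at least 4 interaction genes, except that a log2 fold change of at least 1 left out Mylk4.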

Other observations

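The single genes of other tissues in the last paragraph were chosen after their values were seen; the lists were planned. Members counted here have the same numbers adjusted over the list alone except where others are given.

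The immune and interferon lists here were not called with overload under GFP. Of 26 interferon-stimulated genes 3 rose and 9 fell in TAC+GFP against Sham+GFP (the same adjusted over the list alone; adjusted p = 0.306), with Rsad2 falling 1.69-fold. In TAC+JP2NT against TAC+GFP 3 were higher, Rsad2, Irf9 and Oas2 (8 adjusted over the list alone; adjusted p = 0.0162, and adjusted p = 0.827 with an estimated correlation). The list was not called without TAC+JP2NT replicate 1, 2 or 3 or TAC+GFP replicate 2 (medians 0.15, 0.11, 0.22 and 0.13, from 0.20; adjusted p = 0.16, 0.102, 0.0582 and 0.0669). TAC+JP2NT replicate 4 went the other way: relative to the Sham+GFP mean its mean over the list was -0.33, below the -0.245 to 0.0147 of the TAC+GFP libraries, while the rest of its group had 0.10 to 0.27; without it the median was 0.31. Of 13 MHC class I and processing genes 1 rose and 4 fell with overload under GFP (adjusted p = 0.223), and 1 rose and 4 fell under JP2NT (1 and 6 adjusted over the list alone; adjusted p = 0.0287, adjusted p = 0.631 with an estimated correlation, and, from a median of -0.32, -0.24 and adjusted p = 0.131 without TAC+JP2NT replicate 4). In sham hearts this list was higher with JP2NT (adjusted p = 0.00618, adjusted p = 0.737 with an estimated correlation, and 0.0814 without Sham+GFP replicate 1). Of 8 MHC class II genes measured none was called with overload under GFP by limma (0 adjusted over the list alone; adjusted p = 0.408). Of 15 cytokine and chemokine genes 6 rose and 3 fell (adjusted p = 0.4), with Ccl8 up 7.35-fold and Csf1 down 1.75-fold; between vectors in TAC hearts none was called, and the median of 0.01 and mean of -0.09 differ in sign.

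Stress and timing lists were mixed. Of 20 unfolded protein response genes 2 rose and 8 fell with overload under GFP (adjusted p = 0.28), Atf4 rising 1.82-fold and Hspa5 falling 1.5-fold; under JP2NT 3 rose and 2 fell, and the median of -0.0067 and mean of 0.04 differ in sign. Of 15 oxidative stress response genes 4 rose and 4 fell (adjusted p = 0.771), with Sod2 down 1.75-fold; under JP2NT 6 rose and 5 fell, with a median of 0.20 and a test that points down (adjusted p = 0.998). Of 17 autophagy and lysosome genes 7 rose and 3 fell with overload under GFP (7 and 4 adjusted over the list alone; adjusted p = 0.229), and 2 rose and 6 fell under JP2NT (adjusted p = 0.342). Of 14 angiogenesis genes 1 rose, Hif1a at 2.11-fold, and 5 fell, Kdr at 1.73-fold among them (adjusted p = 0.228); the sham vector median of 0.0099 and mean of -0.02 differ in sign. Of 17 circadian clock genes 6 rose and 5 fell (6 and 6 adjusted over the list alone; adjusted p = 0.811); between vectors in TAC hearts Hlf, Nr1d2 and Tef were higher (6 higher and 3 lower adjusted over the list alone; adjusted p = 0.445), and in sham hearts the list was higher (adjusted p = 0.00332, and adjusted p = 0.521 with an estimated correlation). Also between vectors in sham hearts, hypertrophic stress genes (adjusted p = 0.0262, and adjusted p = 0.737 with an estimated correlation) and immediate early genes (adjusted p = 0.0169, and adjusted p = 0.831 with an estimated correlation) were lower. Fibroblast markers (adjusted p = 0.00245, and adjusted p = 0.536 with an estimated correlation) and atrial cardiomyocyte markers (adjusted p = 0.00332, and adjusted p = 0.737 with an estimated correlation) were higher there. Clock genes and atrial markers were not called without Sham+GFP replicate 1 (0.0549 and 0.0752), nor hypertrophic stress genes without Sham+GFP replicate 2 (0.0759), and all 9 lists called between vectors in sham hearts lost the call without the averaged pair (adjusted p = 0.104 to 0.632). None of the 13 mitochondrially encoded genes is in the table.

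Under JP2NT the overload response of the remaining lists was as follows. Potassium and sodium channel genes fell in 12 of 18 cases and rose in 1 (13 and 2 adjusted over the list alone; adjusted p = 0.000161, and adjusted p = 0.364 with an estimated correlation). TCA cycle genes fell in 14 of 20 (17 adjusted over the list alone; adjusted p = 4.08e-09, and adjusted p = 0.48 with an estimated correlation) and oxidative phosphorylation genes in 17 of 32 (20 adjusted over the list alone; adjusted p = 9.08e-07, and adjusted p = 0.535 with an estimated correlation). Cell cycle genes rose in 16 of 25 and fell in 1 (18 and 1 adjusted over the list alone; adjusted p = 7.49e-06, and adjusted p = 0.535 with an estimated correlation), and immediate early genes rose in 6 of 17 (adjusted p = 0.00991, and adjusted p = 0.636 with an estimated correlation). Cardiomyocyte markers fell in 6 of 14 and rose in 1 (adjusted p = 0.0183, and adjusted p = 0.535 with an estimated correlation), and pericyte markers fell in 3 of 9 (adjusted p = 0.0227, adjusted p = 0.535 with an estimated correlation, and 0.0898 without TAC+JP2NT replicate 4). Of 18 MEF2-related genes 3 rose and 4 fell (3 and 5 adjusted over the list alone), with a median of -0.0089 and a mean of 0.10 (adjusted p = 0.722). Lists whose median, mean and test differ in sign without a call were also adipocyte, neutrophil, mast cell and circadian clock (overload under JP2NT), atrial cardiomyocyte (between vectors in TAC hearts), cardiomyocyte, activated fibroblast, mast cell, erythroid and adipocyte (between vectors in sham hearts), and calcium handling, cytokine and Schwann cell and neuron (interaction).

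Markers of other cell types, with overload under GFP, gave these results. Macrophage markers rose in 3 of 20 cases, Lgals3 among them, and fell in 6, Timd4 among them (adjusted p = 0.735). Endothelial markers rose in 1 of 13 cases, Egfl7, and fell in 5 (adjusted p = 0.489; the median of 0.03 and mean of -0.04 differ in sign), lymphatic endothelial markers rose in 3 of 7 and fell in 1 (adjusted p = 0.262), and smooth muscle markers rose in 1 of 8 and fell in 5 (adjusted p = 0.161). Mesothelial and epicardial markers rose in 5 of 9 cases and fell in 1 (adjusted p = 0.0654), with Krt18 up 6.95-fold and Msln 3.11-fold, and rose in 4 under JP2NT (adjusted p = 0.0183, and adjusted p = 0.535 with an estimated correlation). Schwann cell and neuron markers fell in 6 of 8 cases and rose in 1 (adjusted p = 0.0967), with Sox10 down 3.48-fold, and fell in 5 under JP2NT (6 adjusted over the list alone; adjusted p = 0.0298, adjusted p = 0.535 with an estimated correlation, and 0.0503 without TAC+JP2NT replicate 3). Erythroid markers rose in 3 of 5 cases (adjusted p = 0.0516), Hbb-bt among them. Neutrophil (1 of 5 rose, 0 adjusted over the list alone by limma; adjusted p = 0.463), B cell (1 of 3 rose; adjusted p = 0.306), T cell and NK cell (1 of 3 fell; adjusted p = 0.337), mast cell (1 of 6 rose and 1 fell, 1 and 0 adjusted over the list alone; adjusted p = 0.811), platelet (1 of 4 rose; adjusted p = 0.688) and adipocyte markers (1 of 9 fell; adjusted p = 0.7, with a positive median of 0.38) were not called, and 2 of 10 skeletal muscle markers were abundant enough, too few to test. Without the averaged Sham+JP2NT pair the mesothelial, Schwann cell and neuron, pericyte and MHC class I lists were not called with overload under JP2NT (adjusted p = 0.0669, 0.0735, 0.0689 and 0.204). Atrial cardiomyocyte markers rose in 3 of 10 cases and fell in 2 (adjusted p = 0.628; the median of 0.59 and mean of -0.01 differ in sign).

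The airway genes Bpifa1 and Scgb1a1 had values of 2437 and 890.5 in TAC+JP2NT replicate 2 and of at most 1.33 in every other sample, and the lung surfactant gene Sftpc had 24.1 there, 9.93 in TAC+JP2NT replicate 4 and 0 in the other samples. The atrial genes Myl7 and Sln varied within groups, Myl7 from 249.7 to 3191 and Sln from 98.4 to 1273 in TAC+JP2NT, highest in replicate 4. In TAC+GFP, replicate 3 had 48.6 for the heat shock gene Hspa1a where the other samples of the group had 239.6 to 273.7, and 26.1 for Fos where they had 142.6 to 288.9. In TAC+JP2NT, replicate 3 also had the lowest values of its group, 69.5 for Hspa1a against 136.4 to 202.4 and 15.9 for Fos against 76.7 to 182. Dbp, a clock output gene, ranged from 356.8 in TAC+GFP replicate 1 to 1772 in the averaged Sham+JP2NT pair.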
